A study of Mus musculus with 38 samples.

How the data were processed

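Immunoprecipitated chromatin of mouse liver and isolated mouse hepatocytes was sequenced, and peak lists deposited by the authors were compared. Samples were placed in 15 groups by antibody, source and treatment, from the sample labels, before the data were examined. Of 13 deposited lists, 11 were matched to a group through the library numbers in the list names and the sample descriptions. The other 2 lists, with 8 columns of values, matched no sample and were not used here. Per the submitters' processing notes, reads were processed with CASAVA 1.8 and genome build mm9 was used. The list names speak of hotspot calling, of pooled libraries for the 3 H3K27ac lists, and of a pair of libraries for the other 8 lists. Of those 8 names, 7 give 2 different libraries of the group, and the name of the untreated hepatocyte CREB list gives 1 library against itself. The names of those 8 lists also carry a false discovery rate tag, which the names of the 3 pooled lists lack. The aligner, the other settings of the peak caller and its version are not given in the sources used here.

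Each deposited list gives, per the file headers, the chromosome, start and end of a region, a running number, the highest tag density (a signal), a z-score and a p-value. The authors made the z-score and density for each region with their peak caller, per the file headers and list names, and how the score was scaled is not given in the sources used here. The normalisation behind the authors' density signal is not stated, so it was used only to describe, rank or filter regions within a list. The deposited p-value is the two-sided normal tail of the authors' z-score to within 6.54e-04 on the log10 scale, and was not used further. The running number, another deposited value, exceeds the number of regions in the 8 lists named by a pair of libraries, and equals it in the 3 pooled lists. The number of regions was 65.7% of the highest running number for CREB in fed liver and 72.0% for CREB in glucagon-treated hepatocytes. For the untreated hepatocyte list it was 99.6%. What the running number counts is not stated. Since the filters and the depth behind the lists are not known and may differ, a longer list need not mean more binding.

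Regions of a pair of lists were called shared when they had at least 1 base in common, and otherwise belonged to 1 list only. Shares have 95% Wilson intervals, which cover counting error only. Chance overlap was taken from 1000 circular shifts of the first list along each of 21 chromosomes, with a one-sided permutation p of at least 0.001. The length of a chromosome was taken as the highest region end in the lists. Classes of regions were compared by two-sided Fisher's exact tests with Woolf intervals for the odds ratio, and p-values were adjusted by the Benjamini-Hochberg method over 41 tests between classes and, separately, over 14 tests by rank. Neighbouring regions are not independent, so these p-values are too small, and they describe these lists and not replicated conditions. A threshold of 0.05 was used. The overlap code was tested on simulated lists of 28229 regions, modelled on the comparison of glucagon with glucagon plus corticosterone, and returned the planted counts. Of 40 independent pairs of shorter simulated lists, with regions placed at random and fewer shifts, 3 had a permutation p under 0.05. The permutation test was thus not checked at the length and clustering of the deposited lists. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

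Named regions were chosen by a rule fixed before the data were examined. Per main comparison these were the 5 densest shared regions, by the density in the first list, and the 5 densest regions of each list only, and the text gives the leading ones in full and ranges for the rest. Positions are as the deposited lists give them, in mm9. The lists hold no gene names and the gene table at hand is of another build, GRCm38.p6, so no gene was assigned, and the gene lists, the distances to transcription start sites and the motif searches that had been planned were not run.

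Alternatives fixed before the data were examined were a shared stretch of at least 50% of the shorter region, a gap of up to 500 bp, lists of equal length by density, the upper 50% of each list and shuffled positions for the chance overlap. Added after the data were seen were equal length by z-score, removal of regions at a liver phospho-CREB site, 500 bp windows around midpoints, with or without redrawn classes, removal of chromosomes X and Y, a comparison of the densest liver CREB sites with sites of like width, and the ranking of CREB sites at GR sites.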

Results

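Chromatin immunoprecipitation with sequencing was used to map acetylation of histone H3 at lysine 27 (H3K27ac, a mark of active promoters and enhancers), the cAMP response element binding protein (CREB, a transcription factor activated by glucagon signalling), its phosphorylated form (phospho-CREB) and the glucocorticoid receptor (GR, the nuclear receptor that binds corticosterone). The material was liver of C57BL/6 mice that were fed or fasted for 10 or 24 h, and hepatocytes, the main cell type of liver, isolated from mice and left untreated or given 10 nM glucagon, with or without 1.7 uM corticosterone, for 1 h. The 38 samples formed 15 groups. Peak lists of 11 groups were analysed, 1 list per group. The liver H3K27ac, CREB and phospho-CREB groups held 3 samples each. The hepatocyte groups held 2 samples each, except untreated CREB with 1 sample. The remaining 4 groups, with 10 samples of C/EBPb or GR in fed and fasted liver, were not analysed here. Each list gives 1 value per region and no value per library, and the names of the liver CREB and phospho-CREB lists give 2 of the 3 libraries of their group, so no spread between replicates and no test of a change between conditions could be computed, and every difference below is a difference between lists. The read depth behind the lists is unknown, because the lists give no read counts. The question was how histone acetylation and the binding of these factors in liver differ with fasting, and how the fasting hormones act on CREB binding in hepatocytes.

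The H3K27ac lists of fed and 24 h fasted liver were largely alike. The fed list held 29917 regions and the 24 h list 32103, and 85.4% of the fed regions overlapped a region of the 24 h list (95% Wilson interval 85.0 to 85.8), against 2.66% by chance. The fed list had 4380 regions of its own, covering 2.22 Mb, and the 24 h list had 6526, covering 3.27 Mb. Cut to equal length by density, the lists had 5116 and 5211 regions of their own, and by z-score 4991 and 5159. Lists of equal length give such near parity by construction. Regions of the fed list only were narrow, with a median width of 445 bp against 959 bp for shared regions. The overlap was 32.1 times chance (one-sided permutation p = 0.001, the smallest that 1000 circular shifts can give). The same smallest p was obtained for all 40 pairs of lists compared with shifts.

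The densest H3K27ac regions of these lists lay at the following mm9 positions, where density is the authors' tag density and was used only within a list. The top shared region lay on chromosome 19 from 61275333 to 61275997 with a density of 347.9 in the fed list. The 5 densest shared regions had densities of 255.5 to 347.9 in the fed list, and all 5 also overlapped a CREB site of each of the 3 hepatocyte lists. The 5 densest regions of the fed list only reached 45.3 to 61.8, led by chromosome 17 from 28415601 to 28418024, and all 5 were present in the 10 h list. The 5 densest regions of the 24 h list only reached 61.1 to 83.9. Of these, 4 lay on chromosome Y between 2777647 and 2895935, where 2 also overlapped sites in both CREB and both phospho-CREB lists of liver. The fifth lay on chromosome 15 from 57852863 to 57854742 with a density of 61.1 and a z-score of 106.8. Those on chromosome Y had z-scores of 12.6, 10.5, 9.44 and 8.85, while the lowest z-score of the fed list was 10.9. Regions below that value may be missing from the fed list through its threshold alone.

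The 10 h fasted list was longer than either of the others, with 47777 regions over 52.6 Mb. It contained 92.6% of the fed regions (interval 92.3 to 92.9) and 88.4% of the 24 h regions (88.0 to 88.7). It also held 22324 regions absent from the fed list, 21655 absent from the 24 h list and 18890 absent from both. The lowest z-score was 7.72 in the 10 h list, 8.61 in the 24 h list and 10.9 in the fed list. With the 10 h list reduced to the 29917 densest regions, the length of the fed list, the regions absent from the fed list numbered 7477, and the fed regions absent from it numbered 4862 instead of 2202. Reduced to the 32103 densest regions, the length of the 24 h list, it held 8653 regions absent from the 24 h list. It then lacked 6072 of the 24 h regions instead of 3739.

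Regions of the 24 h list only were less often found at 10 h than regions of the fed list only. The share was 60.7% of 6526 regions (interval 59.5 to 61.8) against 76.9% of 4380 (75.6 to 78.1), an odds ratio of 0.463 (0.425 to 0.504; two-sided Fisher's exact test, p = 5.46e-72). In lists reduced to equal length the shares were 47.4% and 56.0% (odds ratio 0.709, exact p = 3.09e-18). Fisher's exact tests here and below compare classes of regions in these lists, not the conditions.

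GR sites from hormone-treated hepatocytes were more frequent in H3K27ac regions of the 24 h list only than of the fed list only. Of the former, 5.59% overlapped a GR site (interval 5.06 to 6.18), of the latter 2.90% (2.44 to 3.44), and of the shared regions 8.76% (8.42 to 9.11). The odds ratio was 1.98 (1.62 to 2.44; Fisher's exact test, adjusted p = 1.56e-11 over 41 tests). CREB sites of glucagon-treated hepatocytes showed the opposite order, with 18.5% for the 24 h list only and 23% for the fed list only (odds ratio 0.758, adjusted exact p = 9.89e-09). CREB sites of fasted liver overlapped 6.21% of the regions of the 24 h list only and 3.31% of those of the fed list only (odds ratio 1.93, adjusted exact p = 6.08e-12), whereas CREB sites of fed liver gave 6.07% and 5.62% (odds ratio 1.09, interval 0.921 to 1.28, adjusted exact p = 0.348). Phospho-CREB sites of fed liver, however, gave 2.30% and 1.10% (odds ratio 2.12, adjusted exact p = 2.57e-06), and those of fasted liver 1.70% and 0.776% (odds ratio 2.21, adjusted exact p = 2.63e-05). With classes redrawn from 500 bp windows around the midpoints, the GR odds ratio was 1.16 (adjusted exact p = 0.0607), and in the upper 50% of each list the hepatocyte CREB odds ratio was 1.19. For the 10 h list only, GR overlap was 6.09% against 2.04% for the fed list only (odds ratio 3.11, adjusted exact p = 3.19e-18), an odds ratio that depended on the setting: 5.89 with equal length by z-score, 1.43 without regions at phospho-CREB sites (adjusted exact p = 0.0037), 1.04 in the upper 50% of each list and 0.954 with redrawn classes.

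**Figure D1:**
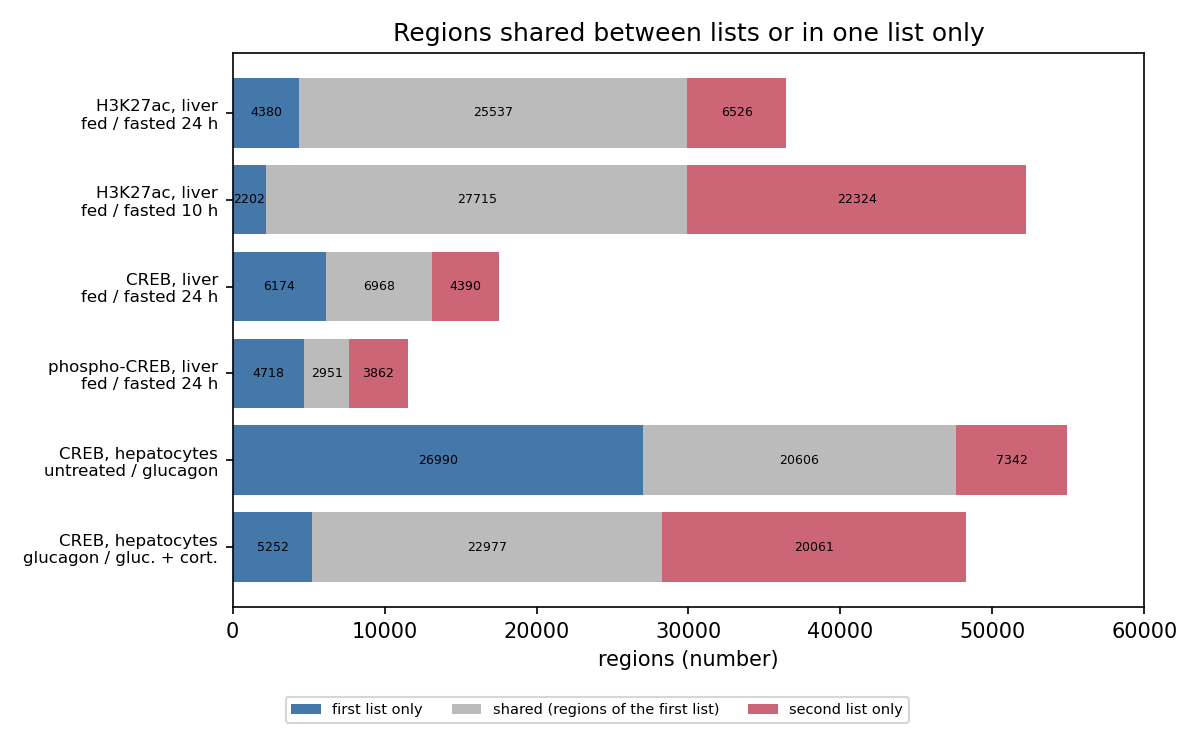
Number of regions (horizontal axis) in the first list only, shared, and in the second list only, for 6 pairs of peak lists, with shared regions counted in the first list. The untreated hepatocyte CREB list had 26990 regions that the glucagon list lacked, and the fed and 24 h fasted H3K27ac lists differed by 4380 and 6526 regions. Lists are whole and of unequal length.

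The CREB list of fasted liver was somewhat shorter than that of fed liver. The fed list held 13142 sites and the fasted list 11339. Of the fed sites, 53.0% overlapped a fasted site (interval 52.2 to 53.9) and 6174 did not. Of the fasted sites, 61.3% overlapped a fed site (60.4 to 62.2) and 4390 did not. The overlap was 95.4 times chance. Sites shared by both lists lay in H3K27ac regions of the fed list at 51.7%, sites of the fed list only at 24.4% (23.3 to 25.4) and sites of the fasted list only at 13.7% (12.7 to 14.8), an odds ratio of 0.494 (0.446 to 0.548; Fisher's exact test, adjusted p = 3.21e-42). Against the H3K27ac list of 24 h fasted liver the shares were 24.3% and 15.7% (odds ratio 0.579, adjusted exact p = 2.47e-27). In lists of equal length these odds ratios were 0.317 and 0.373 by density, and 0.572 and 0.669 by z-score. GR sites went the other way, at 12.4% of the sites of the fasted list only and 7.61% of those of the fed list only (odds ratio 1.72, interval 1.51 to 1.96, adjusted exact p = 4.02e-16). Neither this odds ratio nor those that follow in this paragraph were recomputed under other settings. Phospho-CREB sites of liver had the same order as GR, with odds ratios of 1.75 for the fed and 2.21 for the fasted phospho-CREB list. The hepatocyte CREB lists had the opposite order, with odds ratios of 0.486 to 0.510.

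The densest CREB sites of liver had densities far above the rest of their lists. On chromosome 10 from 121199950 to 121200547 the density in the fed list was 51733, and on chromosome X from 141949414 to 141949966 it was 34285, against 302.5 at rank 100 of that list. Both sites were also in the fasted list. The 5 densest shared sites all overlapped a site in both phospho-CREB lists, and only 1 of the 5, on chromosome 7 from 97590135 to 97590780, overlapped an H3K27ac region or a hepatocyte CREB site. In the fed list, 33 sites had a density over 1000, and 15.2% of them lay in an H3K27ac region of the fed or 24 h list, against 80.9% of the next 1000 sites. The latter were wider, with a median of 1107 bp against 467 bp, and of the 35 among them that were no wider than the widest of the 33 sites, 28.6% lay in such a region (interval 16.3 to 45.1). The densest site of the fed list only lay on chromosome 3 from 135217041 to 135217454 (density 135.5). The densest site of the fasted list only lay on chromosome 7 from 71053979 to 71054412 (density 409.8). Neither site overlapped a region of any other list. The 5 densest sites of the fed list only spanned 96.0 to 135.5, and those of the fasted list only 175.9 to 409.8. Of these fasted-only sites, 1 overlapped a 24 h H3K27ac region and 0 a phospho-CREB site of either list. Of the fed-only sites, 1 overlapped a fed H3K27ac region and 1 a fed phospho-CREB site.

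Phospho-CREB sites of liver were fewer and less often shared. The fed list held 7669 sites and the fasted list 6812. Of the fed sites, 38.5% overlapped a fasted site (interval 37.4 to 39.6), leaving 4718 sites of the fed list only and 3862 of the fasted list only. Sites of the fasted list only lay in H3K27ac regions of 24 h fasted liver at 2.59% (2.13 to 3.14), close to the 1.85% that chance gave for the whole fasted list, whereas sites of the fed list only did so at 15.6% (14.6 to 16.6). The odds ratio was 0.144 (0.117 to 0.179; Fisher's exact test, adjusted p = 4.42e-102). In the longer 10 h H3K27ac list the shares were 10.7% and 24.0% (odds ratio 0.382, adjusted exact p = 3.08e-58), against 2.68% by chance for the whole fasted list. Sites of the fasted list only also overlapped hepatocyte glucagon CREB sites less often, at 4.22% against 20.6% (odds ratio 0.170, adjusted exact p = 6.89e-121). GR overlap was 7.69% and 8.05% (odds ratio 0.951, interval 0.812 to 1.11, adjusted exact p = 0.546).

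Phospho-CREB and total CREB lists from the same feeding state overlapped in part. In fed liver 51.3% of the phospho-CREB sites lay at a CREB site (interval 50.2 to 52.4) and in fasted liver 47.0% (45.9 to 48.2), leaving 3735 and 3608 phospho-CREB sites outside the CREB lists. Conversely, 29.3% of the fed CREB sites and 27.4% of the fasted CREB sites lay at a phospho-CREB site. Both overlaps were 80.4 times chance.

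In isolated hepatocytes the CREB list of untreated cells was longer than that of glucagon-treated cells. It held 47596 sites against 28229. Of the glucagon sites, 74.0% overlapped an untreated site (interval 73.5 to 74.5) and 7342 did not, while 26990 untreated sites were absent from the glucagon list. The list names give a single library paired with itself for untreated cells and a pair of libraries for glucagon, so the lists may have passed different filters. With the untreated list reduced to the 28229 densest sites, the untreated-only sites numbered 9752 and the glucagon-only sites 9317, near parity as lists of equal length give by construction. The strongest CREB sites were shared. On chromosome 7 from 52972681 to 52974281 the density in the list of untreated cells was 1042, and on chromosome 8 from 126472502 to 126474148 it was 946.6. All 5 of the densest shared sites were also in both liver CREB lists, both phospho-CREB lists and all 3 H3K27ac lists.

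Sites of the glucagon list only lay at GR sites more often than sites of the untreated list only, and less often than shared sites. Of these 7342 sites, 11.9% overlapped a GR site of cells given glucagon and corticosterone (interval 11.2 to 12.7), against 4.08% of the untreated-only sites (3.85 to 4.33) and 17.1% of the shared sites (16.6 to 17.7). The odds ratio of glucagon-only over untreated-only sites was 3.18 (2.90 to 3.49; Fisher's exact test, adjusted p = 2.19e-121), and 7.40 with equal length by density, 2.55 with equal length by z-score and 9.89 in the upper 50% of each list. Of the 5 densest glucagon-only sites, 4 overlapped a GR site, all 5 were also in the list for glucagon plus corticosterone, and none overlapped a liver H3K27ac region. The densest of these lay on chromosome 19 from 53495224 to 53496249 (density 172.0). The next lay on chromosome 6 from 149118837 to 149119947, on chromosome 7 from 107827767 to 107828913, on chromosome 13 from 118847333 to 118847949 and on chromosome 15 from 95734376 to 95735595. Glucagon-only sites lay in H3K27ac regions of 24 h fasted liver less often than untreated-only sites, at 16.8% against 21.5% (odds ratio 0.739, adjusted exact p = 7.22e-19). This odds ratio was 0.236 with equal length by density, 0.912 with equal length by z-score, 0.360 in the upper 50% of each list and 0.941 with classes redrawn from 500 bp windows (adjusted exact p = 0.0607).

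Corticosterone added to glucagon gave a longer CREB list, of 42090 sites over 31.2 Mb. It contained 81.4% of the glucagon sites (interval 80.9 to 81.8), lacked 5252 of them and held 20061 sites that the glucagon list did not. Reduced to 28229 sites, it held 8095 such sites and lacked 7105 of the glucagon sites. The densest sites of the corticosterone list that the glucagon list lacked lay on chromosome 3 from 78996575 to 78998617 (density 212.3) and on chromosome 13 from 52831266 to 52832289 (density 180.2). All 5 of the densest sites of the corticosterone list only overlapped a GR site. Among the 5 densest glucagon-only sites, with densities of 20.5 to 30.4, 2 overlapped a GR site.

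The share of these CREB sites at GR sites depended on the strength of the sites. In the whole lists, 4.48% of the sites of the corticosterone list only overlapped a GR site (interval 4.2 to 4.78), fewer than the 6.38% of the glucagon-only sites (5.75 to 7.07), with an odds ratio of 0.689 (0.605 to 0.784; Fisher's exact test, adjusted p = 3.79e-08). Shared sites overlapped at 17.5%. In lists of equal length the odds ratio was 1.04 (adjusted exact p = 0.536), or 1.65 with the length set by z-score, and in the upper 50% of each list it was 2.73 (adjusted exact p = 8.31e-15). With a gap of 500 bp it was 0.627, and with classes redrawn from 500 bp windows 0.462 (adjusted exact p = 7.21e-42). Sites of the corticosterone list only had a median width of 449 bp, against 339 bp for the glucagon-only sites. Among the 10000 densest sites of each list, 205 of the 454 sites absent from the whole glucagon list overlapped a GR site (45.2%, interval 40.6 to 49.8), against 11 of the 76 sites absent from the whole corticosterone list (14.5%, 8.28 to 24.1). The odds ratio was 4.86 (2.50 to 9.46; Fisher's exact test, p = 1.42e-07, adjusted p = 2.48e-07 over 14 tests by rank). Among the 20000 densest the shares were 12.98% and 5.53% (odds ratio 2.55, interval 1.94 to 3.35), and among the 5000 densest 95 of 120 and 2 of 3 sites (odds ratio 1.90, interval 0.166 to 21.8, adjusted exact p = 0.513). This ranking was chosen after the data were seen and was not matched for width. In the same ranking, glucagon-only sites among the 10000 densest overlapped GR at 36.6% and untreated-only sites at 3.73% (odds ratio 14.9, adjusted exact p = 1.79e-43), and among the 20000 densest at 17.2% and 2.63% (odds ratio 7.70). Among the 5000 densest, with 26 untreated-only sites, the shares were 50.7% and 3.85% (odds ratio 25.7, interval 3.39 to 195.4).

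**Figure D2:**
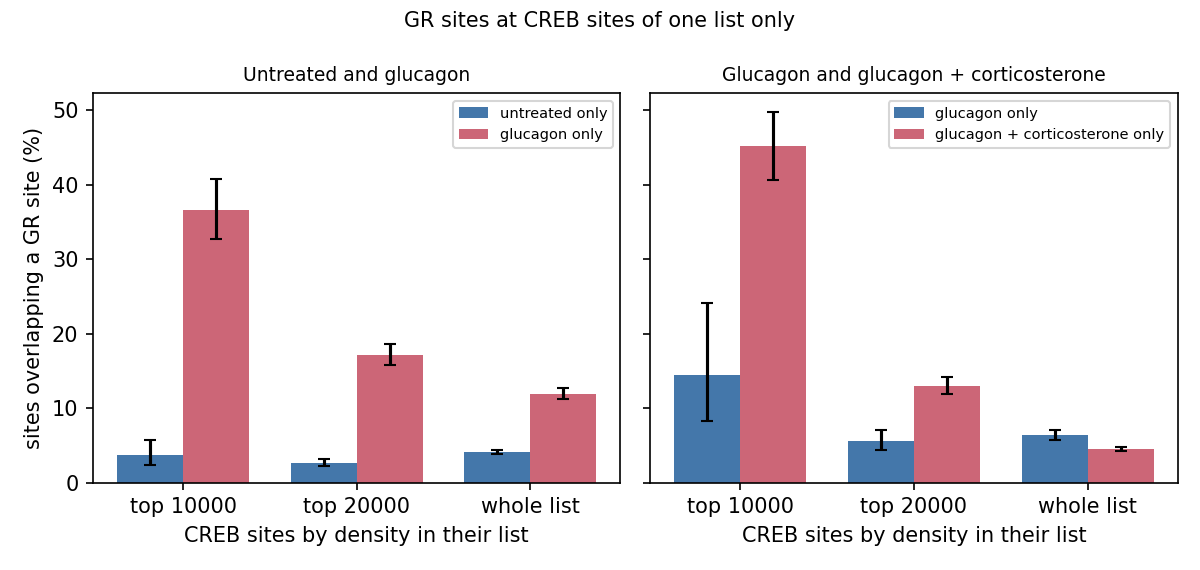
Share of CREB sites present in one hepatocyte list and absent from the whole other list that overlap a GR site (vertical axis, %), among the 10000 or 20000 densest sites of each list and in whole lists. Bars are shares, and error bars are 95% Wilson intervals that cover counting error only. Sites of the corticosterone list only are at 45.2% among the 10000 densest sites and at 4.48% in the whole list.

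Seen from the GR sites, CREB was present at a minority of all sites and at most of the strongest. Of the 11892 GR sites, 42.7% overlapped a CREB site of the same treatment (interval 41.8 to 43.6), 37.1% one of glucagon alone (36.2 to 38) and 39.1% one of untreated cells (38.2 to 39.98), against 1.93%, 1.19% and 1.88% by chance. With CREB lists reduced to 28229 sites, these shares were 38.7%, 37.1% and 27.2%. Of the 1000 densest GR sites, 92.2% (90.4 to 93.7), 83.4% (81.0 to 85.6) and 77.4% (74.7 to 79.9) overlapped a CREB site of the 3 lists in that order. The densest shared GR site lay on chromosome 4 from 150058675 to 150059968, with a GR density of 300.5, and overlapped a CREB site in all 3 lists. Of the 5 densest GR sites without CREB, 4 lay on chromosome X and the fifth on chromosome 9 from 13422449 to 13423042. All 5 overlapped regions of every liver list, for H3K27ac, CREB and phospho-CREB. Whether these are sites of GR or regions that recur with several antibodies was not tested. The densest CREB site without GR lay on chromosome 8 from 126472361 to 126474149 (density 773.9).

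Of the CREB sites of liver, a little under 50% lay at a hepatocyte CREB site, and of those of hepatocytes a smaller share lay at a liver site. Of the fed liver sites, 48.9% overlapped an untreated hepatocyte site (interval 48.0 to 49.7), leaving 6722 outside. Of the fasted liver sites, 43.8% overlapped a glucagon site (42.9 to 44.8), leaving 6367 outside, and 44.7% overlapped a site of glucagon plus corticosterone (43.8 to 45.6). Conversely, 13.3% of the untreated hepatocyte sites overlapped a fed liver site, and 17.4% of the glucagon sites and 11.8% of the sites of glucagon plus corticosterone overlapped a fasted liver site. These overlaps were 24.4, 35.2 and 22.4 times chance.

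Factor sites differed in how often they lay in acetylated chromatin. CREB sites of fed liver lay in H3K27ac regions of fed liver at 38.9% (interval 38 to 39.7), and CREB sites of fasted liver in those of 24 h fasted liver at 39.2% (38.3 to 40.1), against 1.90% and 2.00% by chance. Phospho-CREB sites did so at 18.8% in fed liver (17.9 to 19.6) and at 13.1% in 24 h fasted liver (12.3 to 13.9), or at 8.78% and 5.43% with lists of equal length. In the longer 10 h H3K27ac list the shares were 39.7% and 34.1% for phospho-CREB sites of fed and fasted liver. For CREB sites of fed and fasted liver they were 55.0% and 54.8%. The phospho-CREB overlaps with the 10 h list were 14.6 times chance (fed) and 12.7 times (fasted). They were 10.5 times chance for fed sites in the fed list and 7.08 times for fasted sites in the 24 h list. For CREB the folds were 18.8 and 18.9 at 10 h, against 20.5 and 19.6. The phospho-CREB overlap thus rose by more than chance overlap did. Set against H3K27ac of 24 h fasted liver, which is another source than the cultured cells, hepatocyte CREB sites overlapped at 50.5% with glucagon (49.95 to 51.1) and at 44.1% with glucagon plus corticosterone (43.7 to 44.6), and GR sites at 21.8% (21.1 to 22.6). The order of these CREB lists depended on the setting. With each CREB list and the H3K27ac list cut to the shorter of both, the shares were 49.3% for glucagon and 53.8% for glucagon plus corticosterone, and with the upper 50% of each list 55.6% and 49.0%. With the upper 50% of both the factor and the H3K27ac list the shares were higher than in whole lists for CREB in fed and fasted liver, at 52.1% and 57.0%, and for GR, at 33.6%. Both lists were cut at once there, so the effect of site strength alone was not measured. The fed liver CREB sites with a density over 1000 lay in an H3K27ac region of the fed or 24 h list at 15.2%.

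**Figure D3:**
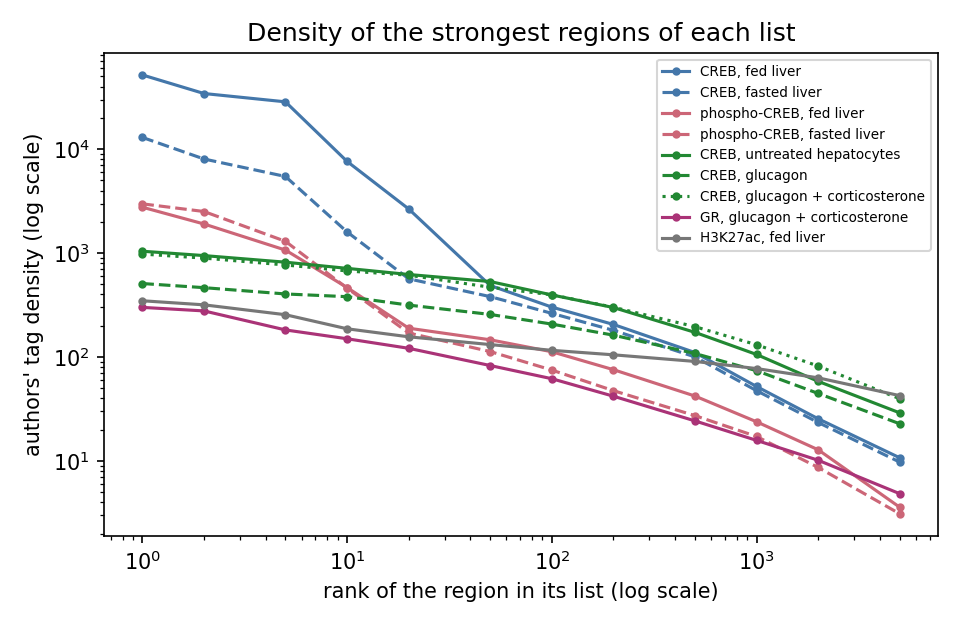
The authors' tag density (vertical axis, log scale) of the regions at fixed ranks (horizontal axis, log scale) in 9 of the peak lists, where each line is a list and levels are not compared between lists. The liver CREB and phospho-CREB lists rise steeply at the top, in the fed liver CREB list from 302.5 at rank 100 to 51733 at rank 1.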

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

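No paired analysis was possible because each list gives a single value per region, so leaving out replicates, a replicate block, a pseudocount and a filter on low values could not be applied. Settings by position relative to genes and by motif were not run. The settings by z-score, without phospho-CREB sites, with 500 bp windows and without chromosomes X and Y were chosen after seeing the data. Of 89 odds ratios recomputed under an alternative, 80 kept their direction and their side of the threshold, and all 40 folds over chance moved by less than 1.5 times with shuffled positions. Those 89 values belong to 10 of the 41 odds ratios between classes. The rest of the 41 were not recomputed. The depth of the libraries is unknown, so weak regions missing from a list may lie below its threshold. With a gap of 500 bp, regions of the fed list missing at 10 h fell from 2202 to 1438. The cause was not tested for any change below, except that shorter lists hold fewer regions by construction.

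With the upper 50% of each list, regions in 1 list only numbered 1770 (fed) and 2876 (24 h) for H3K27ac, 513 (fed) and 9881 (10 h), and 9167 (10 h) and 912 (24 h). For CREB in liver they numbered 1848 (fed) and 970 (fasted), for phospho-CREB 1655 and 1235, for phospho-CREB without CREB 1210 in fed and 1509 in fasted liver, for untreated and glucagon cells 11491 and 1778, for glucagon and corticosterone 873 and 8103, for GR without CREB 1798, and for fed and fasted liver CREB outside hepatocyte lists 1693 and 1723. With equal length by density, the counts were 4862 (fed) and 7477 (10 h), 8653 (10 h) and 6072 (24 h), 9752 (untreated) and 8095 (corticosterone). By z-score they were 4815, 7632, 8964, 6143, 10627 and 7758 in the same order. Without sites at phospho-CREB sites, fed and fasted liver CREB outside hepatocyte lists numbered 4111 and 3426.

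In the upper 50% of each list, the odds ratio of hepatocyte glucagon CREB overlap between H3K27ac regions of the 24 h and the fed list only turned from 0.758 to 1.19, and that of GR overlap for the 10 h list fell from 3.11 to 1.04 (1.43 without regions at phospho-CREB sites, 5.89 with equal length by z-score). That of GR overlap for corticosterone-only over glucagon-only CREB sites turned from 0.689 to 2.73, and also to 1.04 with equal length and to 1.65 with equal length by z-score. That of 24 h H3K27ac overlap for the same sites turned from 1.98 to 0.838 (3.33 with equal length). That of GR overlap at glucagon-only sites was 7.40 with equal length, 2.55 with equal length by z-score and 9.89 in the upper 50%, and that of H3K27ac overlap 0.236, 0.912 and 0.360. With equal length, those of H3K27ac at liver CREB sites were 0.317 and 0.373, and by z-score 0.572 and 0.669. With classes redrawn from 500 bp windows, the odds ratios were 1.16 for GR at 24 h, 0.954 for GR at 10 h, and 0.941 for H3K27ac at glucagon-only sites. With windows used for the overlap and classes kept, all 10 odds ratios kept their call. Shares in H3K27ac regions for CREB in fed liver, CREB in fasted liver and GR were 35.4%, 35.7% and 19.1% with 50% of the shorter region, 40.7%, 40.8% and 23.9% with a gap of 500 bp, 28.3%, 27.4% and 14.9% with equal length, and 52.1%, 57.0% and 33.6% in the upper 50%. For CREB with glucagon and with corticosterone as well they were 49.3% and 53.8% with equal length and 55.6% and 49.0% in the upper 50%. For phospho-CREB in fed and fasted liver they were 8.78% and 5.43% with equal length and 27.5% and 18.9% in the upper 50%.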

Other observations

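A set of 3980 CREB sites of the glucagon list (14.1% of it) was present in all 5 CREB lists of liver and hepatocytes. These sites lay in H3K27ac regions of 24 h fasted liver at 83.7% (95% Wilson interval 82.5 to 84.8), against 45.1% (44.5 to 45.7) of the other sites of the glucagon list, an odds ratio of 6.24. In fed liver the shares were 81.0% and 44.7%. The sites were wider, with a median of 1025 bp against 542 bp, and their median density was 36.6 against 9.48. With 500 bp windows around midpoints the odds ratio for 24 h fasted liver was 5.54. Fed liver phospho-CREB overlapped 35.7% of them and 1.19% of the other sites. The set was chosen for lying in both liver CREB lists, and 29.3% of all fed liver CREB sites lay at a fed liver phospho-CREB site. The contrast in phospho-CREB therefore follows largely from that choice, and the contrast in liver H3K27ac may do so in part. GR overlap was close in both sets, at 16.8% and 15.2%, with an odds ratio of 1.13 (1.03 to 1.24).

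Phospho-CREB sites shared by fed and fasted liver overlapped the 10 h H3K27ac list at 64.8%, against 25.1% for the fed and 27.3% for the 24 h H3K27ac list. Chromosome X held 14.0% of the phospho-CREB sites of fasted liver and 12.9% of those of fed liver, 9.72% and 8.59% of the CREB sites of fasted and fed liver, 5.32% of the GR sites, 4.22% of the 10 h H3K27ac regions, 4.09% of the untreated hepatocyte CREB sites and 2.49% to 3.02% of the regions of the other 4 lists.

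For the 3 patterns that follow, the tests on H3K27ac at the densest liver CREB sites and at the strong corticosterone-only sites were fixed before their results were seen, and the other tests, with the comparison at like width, only after.

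The fed liver CREB list had 33 sites with a density over 1000, all of which were also in the fasted CREB list. Of these, 15.2% lay in acetylated chromatin (interval 6.65 to 30.9) against 80.9% of the next 1000 sites (78.8% for 500 bp around the midpoints), less than had been set for CREB binding of the liver. The next 1000 sites are wider, however, and 28.6% of the 35 that are as narrow lay there (16.3 to 45.1). Those 35 come from the same list below the cut on density and may hold sites of the same kind, so they are no independent reference. The share thus could not decide, and CREB binding stays open. Collapsed repeats in the genome build would appear with every antibody, and 3.03% of these sites were in both the GR list and an H3K27ac list (0.537 to 15.3), which argues against them. DNA added to the liver libraries of one preparation may account for them: 6.06% were in the untreated hepatocyte CREB list (90.9% of the next 1000 sites, but 14.3% of the 35 narrow ones) and 75.8% in a liver phospho-CREB list (94.4% and 62.9%), so neither share sets them apart from sites as narrow and this stays open. The labels give no preparation batch.

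The untreated hepatocyte CREB list was longer than the glucagon list. Lack of a concordance filter on the single untreated library stays open: the highest running number of the glucagon list was 0.820 times that of the untreated list, but what this number counts is not stated, and the untreated list, paired with itself, also lacks 179 of its numbers. Weak regions at the end of the untreated list stay open as well, since 76.8% of the untreated-only sites lay in the lower 50% of that list by density, but so did 84.6% of the glucagon-only sites in theirs. The depth of the libraries and an effect of glucagon itself stay open, untested.

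Strong CREB sites of the corticosterone list only lay at GR sites at 45.2%. Among the 10000 densest sites, their odds ratio of lying in an H3K27ac region of 24 h fasted liver was 0.4999 (0.304 to 0.821) relative to 76 glucagon-only sites. The shares there were 43.4% and 60.5%, so more frequent acetylation in fasted liver does not account for the pattern at that cut. Whether GR overlap differs between acetylated and other sites within these classes was not tested, so no wider conclusion on acetylation is drawn. More frequent acetylation stays open among the 20000 densest, with 1.12 (0.982 to 1.29) where the odds ratio of GR overlap was 2.55. In whole lists GR overlap was no higher (0.689) although H3K27ac overlap was (1.98). The lists hold no acetylation or accessibility of the treated cells, so generally accessible chromatin in those cells stays open. Without sites at liver phospho-CREB sites the odds ratio of GR overlap was 25.5 (6.17 to 105.6), so regions that recur in those liver lists do not account for the pattern. The rise from 4.86 came from the glucagon-only sites, of which 2 of 65 then overlapped GR, against 11 of 76 before. Of the 454 corticosterone-only sites 449 remained, and 201 of them overlapped GR. These sites are absent from the glucagon list by definition, so the test could hardly find regions that recur with every antibody among them. Carry-over of GR chromatin into the corticosterone CREB libraries may be a source. Of the 200 densest GR sites, 1.0% were missing from the corticosterone CREB list, but 6.5% were missing from the glucagon list and 10.0% from the untreated list. The test thus left little room to tell and this stays open. A like excess was seen without corticosterone, at 36.6% of the glucagon-only and 3.73% of the untreated-only sites among the 10000 densest (odds ratio 14.9). Carry-over into the corticosterone libraries would not account for that excess. CREB binding next to GR in cells given corticosterone stays open, untested.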
